A study of Homo sapiens with 2 samples.

How the data were processed

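Chromatin immunoprecipitation with sequencing was carried out on untreated Jurkat cells, per the labels' protocols. Nuclear fractions were digested with micrococcal nuclease at 1.5 U per microlitre, nuclear complexes were isolated with an antibody against PHF6 (HPA001023), and libraries were made with a Diagenode MicroPlex kit and sequenced on an Illumina NextSeq instrument. There were 2 libraries, 1 of WT and 1 of PHF6KO cells. Samples were grouped by the genotype label.

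The submitters' processing notes name Bowtie2, SAMtools, SICER and deepTools 3.3.0, and the build hg19. SICER calls broad enriched domains from reads counted in windows. Which tool made the list, its settings and which library or input served as the control are not given in the sources used here. The name of the deposited list carries a fold tag of 1.5, an FDR tag of 20 and a tag for no Y, and the list held 0 islands on Y. How the tags were applied is not given. The authors deposited coordinates only: the 3 columns are the chromosome, start and end of each island, with no fold, score or p-value. All 11528 starts were multiples of 1000 bases and all ends closed a window of 1 kb, so positions are known to 1 kb. Neighbouring islands were never closer than 4 kb, a spacing shared by 579 pairs. No island was listed more than once. Islands ran past the chromosome length on 0 chromosomes of hg19 and on 13 chromosomes of GRCh38, which matched the stated build. Starts are printed 1-based.

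Because reads per island and per library were not used here, depth and counting error are unknown and no interval is given. A list filtered on fold or FDR holds no measure of how strongly an island was enriched, and a fixed window and joining distance set the shortest gap and affect island length. Sequence repeated across the genome, such as satellite arrays, is largely unassembled in hg19, so reads from it cannot be placed uniquely and a list of islands says little about it.

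Chromosome lengths and stained cytogenetic bands of hg19 came from the UCSC band table in the R package circlize 0.4.16. Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9. A table of assembly gaps was not used here. In its place, 24 island-free stretches of at least 3 Mb that touch a centromere, variable or stalk band were left out (188 Mb). This left 2848 Mb for placement. All but the stretch from 1 to 9411000 of chromosome 21 touch a centromere band and were taken as centromeric gaps. Since the stretches left out were delimited from the list, each inner edge is an island. In each of 1000 placements the islands of the list, with their lengths, were laid at random without overlap and at least 4 kb apart. Placement ran over the whole genome for chromosomes and bands, and within each island's own chromosome for distances, clustering and stain classes. Island length by chromosome was tested by permuting lengths over islands. The two-sided permutation p from these placements doubled the smaller tail, with 0.0020 the smallest value possible, and was adjusted by the Benjamini-Hochberg method over 23 chromosomes, 762 bands, 7 stain classes or 28 distance comparisons, with a threshold of 0.05. The p-values over a single list treat islands as independently placed, which clustered islands are not, so the placement ranges are narrow.

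The tests of chromosome density, of distance from centromeric gaps and of clustering, and the naming of the 10 longest islands and of the 3 chromosomes with the highest and the 3 with the lowest relative density, were fixed before the data were examined. Bands, stain classes, chromosome ends, island lengths by chromosome and island-free stretches were added after seeing the data, and so was the rule for placement outside centromeric stretches. The tests of satellite sequence, of repeat and GC content, of gene features and of 24 gene lists were also planned. They need sequence or genes of hg19, and since the annotation used here is of GRCh38.p14 they were not run, no gene was assigned to an island and the planned naming of genes was dropped.

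The procedure was tested on simulated data with 10 lists of uniformly placed islands of the real lengths. It called 1 of 230 chromosome tests and 0 of 7620 band tests after adjustment, and at an unadjusted 0.05 it called 1 of 10 centromere tests and 2 of 10 clustering tests. A planted rise of density to 1.5 times was found in 20 of 20 chromosomes and a fall to 0.5 times on X in 10 of 10 lists. These simulations kept the gaps of the real list and placed islands without clustering. They therefore do not test gaps delimited from islands, or false calls in a clustered list. Alternatives tried were a stricter list of islands at least as long as the median, islands merged within 1 kb, autosomes only, other distances, covered bases and other placements. A further alternative was the list without islands that border a stretch left out, called islands that border a gap below.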

Results

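PHF6 is a plant homeodomain finger protein of the nucleus and nucleolus, and its gene is recurrently mutated in T cell acute lymphoblastic leukaemia. Where PHF6 sits on chromatin was examined in untreated Jurkat cells, a human T cell leukaemia line, by immunoprecipitation of nuclease-digested chromatin with an antibody against PHF6 followed by sequencing. There was 1 library of cells with intact PHF6 (WT) and 1 library of PHF6 knockout cells (PHF6KO). With 1 library per genotype no spread between cultures was measured and no test between the genotypes was made. The deposited list gives 11528 enriched regions, called islands here, by chromosome, start and end on the hg19 build. It carries no height, fold, p-value or read count for any island and no value per library, so the depth behind each island is unknown and the knockout label was not checked against the list. Random placements of the same islands served as the background throughout, and every permutation p from them describes how islands lay within this list, not how they would vary between cultures.

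Islands were broad. Their median length was 14 kb, with quartiles of 8 and 23 kb and a range of 1 to 549 kb, and together they covered 235 Mb, or 8.27% of the bases open to placement. The 185 islands of at least 100 kb held 12.6% of all covered bases, and 34 of them lay on chromosome 19. The longest island, of 549 kb, spanned positions 68126001 to 68675000 of chromosome 7 in band 7q11.22. It was followed by a 491 kb island at 10698001 to 11189000 of chromosome 21, in the short-arm bands 21p11.2 and 21p11.1 of that acrocentric chromosome. Of the 10 longest islands, 7 lay on chromosome 19. They included 413 kb at 52283001 to 52696000 and 322 kb at 52802001 to 53124000 in 19q13.41, 374 kb at 20131001 to 20505000 and 373 kb at 21510001 to 21883000 in 19p12, and 373 kb at 58420001 to 58793000 in 19q13.43. The others on chromosome 19 were 363 kb at 37444001 to 37807000 in 19q13.12 and 326 kb at 53602001 to 53928000 in 19q13.42. The remaining island of the 10 had 327 kb at 57155001 to 57482000 of chromosome 7, in 7p11.2 beside the centromere. Genes, exons and repeats inside these islands were not assigned, because the annotation used here is of another build.

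Chromosome 19, the most gene-dense human chromosome, held 6.51 islands per Mb, 1.60 times the median of random placements, and chromosome X held 1.49 per Mb, 0.37 times that median. Chromosomes 21 and 22 had the next highest density relative to placement, at 5.90 and 5.08 islands per Mb (1.47 and 1.25 times). The lowest after X were chromosome 13, at 3.49 per Mb (0.87 times), and chromosome 17, at 3.50 per Mb (0.87 times), of which chromosome 13 passed the test (adjusted permutation p = 0.038) and chromosome 17 did not (adjusted permutation p = 0.052). Over 23 chromosomes and 1000 placements, 4 chromosomes (14, 19, 21 and 22) were higher and 2 (13 and X) lower in a two-sided placement test with Benjamini-Hochberg adjustment. The adjusted p was 0.011 for chromosomes 14, 19, 21 and X, the smallest these placements can give in this family. By covered bases the contrast was wider: islands covered 28.1% of chromosome 19, 14.8% of chromosome 21 and 2.05% of chromosome X, against a placement median near 8.25%. Chromosomes 7, 16 and 22 were also higher by this measure (1.28, 1.37 and 1.39 times), and chromosomes 2, 3, 13 and 18 lower (0.81, 0.86, 0.75 and 0.78 times). Mean island length was above permuted lengths on 4 chromosomes (7, 16, 19 and 21) and below on 7 (2, 4, 5, 6, 11, 18 and X). It differed most on chromosome 19, with a mean of 43.1 kb against 20.3 kb when lengths were permuted over all islands (range of 95% of permutations 18.1 to 23.1 kb). On X the mean was 13.8 kb (permuted range 17.5 to 24.1 kb). A second set of 1000 placements called 6 chromosomes higher and 3 lower, and the stricter list of longer islands called 8 higher and 5 lower. Without X, 2 were higher and 5 lower, with chromosomes 14 and 22 no longer called (adjusted permutation p = 0.083 and 0.055). Chromosome 14 also lost its call in the stricter list and by covered bases (both 0.14), and with placement over whole chromosome lengths chromosomes 14 and 21 (1.01 and 1.15 times) lost theirs and chromosome 22 turned to 0.92 times.

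**Figure D1:**
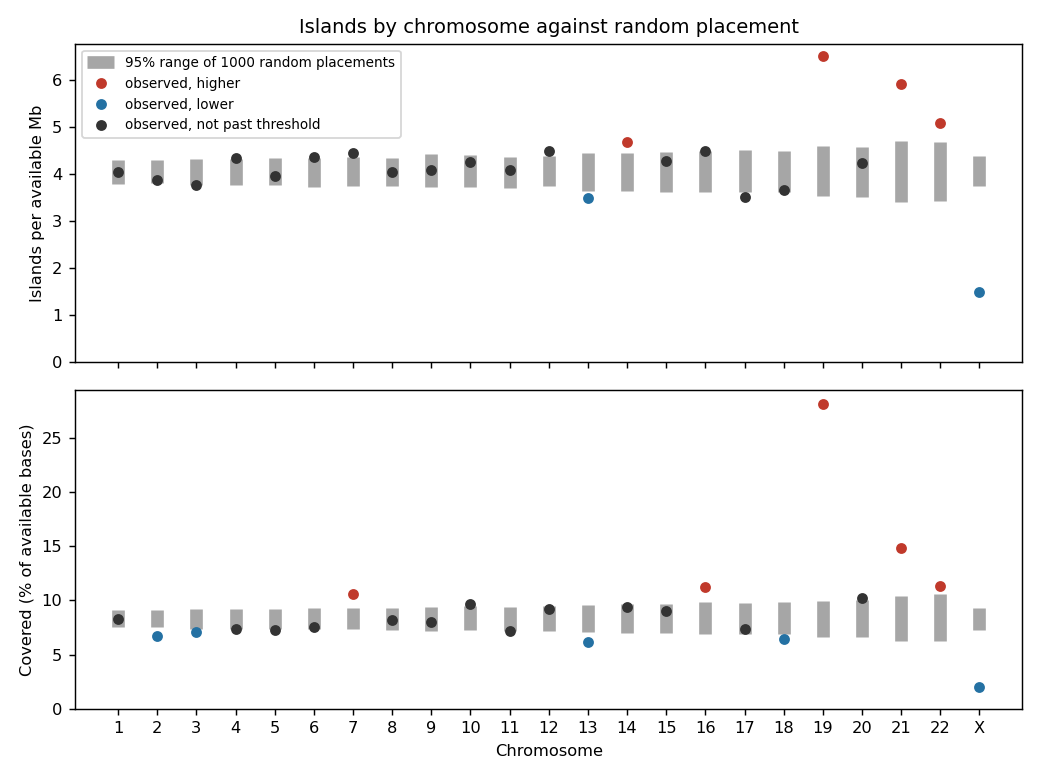
Islands per available Mb (top) and percent of available bases covered by islands (bottom) for each chromosome, as points coloured by the placement test, with grey bars for the 95% range of 1000 random placements. Chromosome 19 stands at 6.51 islands per Mb and 28.1% covered, chromosome X at 1.49 islands per Mb and 2.05% covered.

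Within chromosome 19 the covered bases were unevenly spread over its bands. In 19p12, a band beside the centromere known for its cluster of zinc finger genes, 50 islands covered 85.2% of the bases, against a placement median of 7.77% (95% range 3.82 to 15.4%). Islands covered 60.8% of 19q13.12, 53.9% of 19q13.41, 52.8% of 19q13.43, 42.0% of 19q13.31, 28.2% of 19p13.2 and 26.1% of 19q13.42. All 7 of these bands were above placement after adjustment over 762 bands of at least 1 Mb (adjusted permutation p = 0.045 for 19q13.42 and 0.018 for the others, the smallest possible here). The other 8 tested bands of chromosome 19 did not pass. Of these, 19p13.12 at 25.5%, 19q13.11 at 20.2% and 19p13.11 at 15.5% still lay above their 95% placement ranges (adjusted permutation p = 0.052, 0.066 and 0.14). Band 19q12 at 10.4% lay inside its range. Bands 19q13.32 at 7.57%, 19q13.2 at 8.40%, 19q13.33 at 8.79% and 19p13.3 at 8.94% were near the genome-wide placement median. When each island was kept on its own chromosome, 19p12 and 19q13.12 still passed (3.08 and 2.21 times their placement median). Bands 19q13.31, 19q13.41 and 19q13.43 stayed above the median (1.56, 1.95 and 1.97 times) without passing (adjusted permutation p = 0.38, 0.077 and 0.057), and 19p13.2 and 19q13.42 stood at 1.00 and 0.94 times. Against their own chromosome 5 bands were lower, 19p13.3, 19q12, 19q13.2, 19q13.32 and 19q13.33, at 0.27 to 0.38 times (adjusted permutation p = 0.019 to 0.043).

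**Figure D2:**
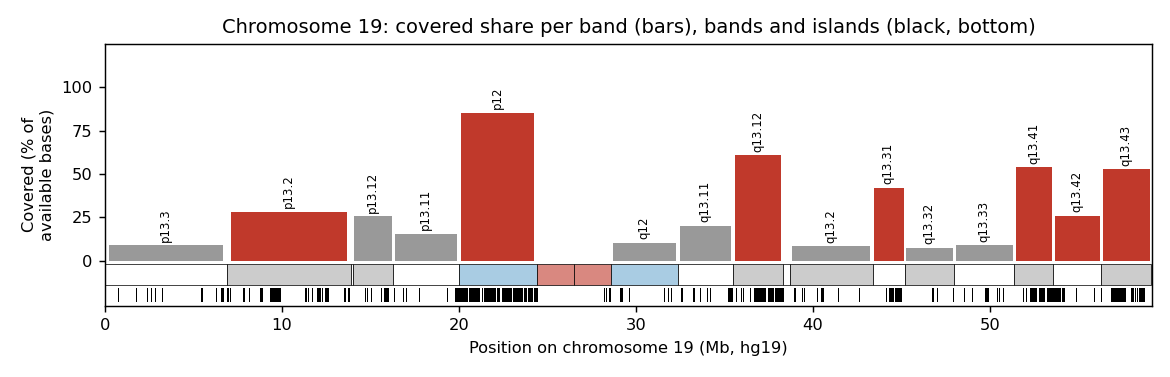
Percent of available bases covered by islands in each tested band of chromosome 19 (bars, red where above random placement after adjustment), with the stained bands and the islands (black) drawn to scale along the chromosome in Mb of hg19. The tallest bar is 19p12 at 85.2%, and 19q13.32 is the lowest at 7.57%.

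Outside chromosome 19, 33 further bands were more covered than placed, which made 40 in all, and 95 bands were less covered. Band 21p11.2, on the short arm of chromosome 21 that also carries satellite and ribosomal DNA arrays, was covered over 74.3% of its available bases by 12 islands. Bands at or beside other centromeres followed, with 50.3% of the available bases of 10p11.1, 44.7% of 7p11.2, 38.9% of 7q11.21 and 30.6% of 4p11. Only 1.49 Mb of 21p11.2, 1.155 Mb of 10p11.1 and 1.46 Mb of 4p11 were available, beside stretches left out whose edges are islands. Band 4p11 held 3 islands. With placement over whole chromosome lengths the ratios of 21p11.2 and 10p11.1 fell from 10.1 and 7.13 to 3.65 and 3.72 times, both still called. That value was not examined for 4p11. Along chromosome arms, islands covered 48.2% of 7q11.22, 46.3% of 3p23 and 39.5% of 8q24.21, the band that holds the MYC oncogene. They covered 38.7% of 4q35.2, the subtelomeric band with the D4Z4 repeat array, 35.8% of 12q24.33 and 23.1% of 14q32.2, the band of the T cell transcription factor gene BCL11B. The adjusted p was 0.018 for each of these bands. The band names single out regions of several Mb and say nothing of which gene in them an island met. These bands were picked after their values were seen, and not by rank alone. Bands 16p13.12 at 36.5% and 20q13.31 at 34.4%, for example, were more covered than 14q32.2.

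**Figure D3:**
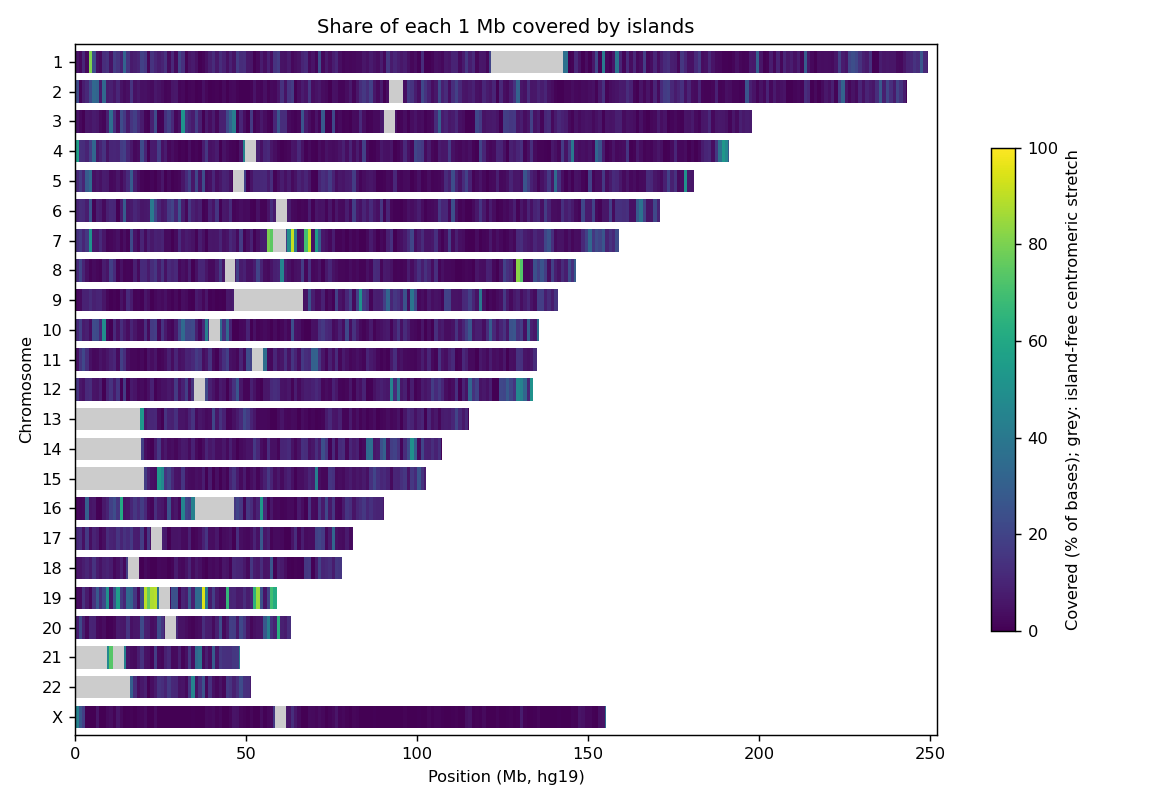
Percent of each 1 Mb stretch of hg19 covered by islands (colour, 0 to 100%) along chromosomes 1 to 22 and X, with the island-free centromeric stretches left out of placement in grey. Bright stretches include 19p12 (85.2% of its available bases covered), 21p11.2 (74.3% of the 1.49 Mb available) and 7q11.22 (48.2%). Most of chromosome X is dark, with 20.7% of Xp22.33 and 10.7% of Xq11.2 covered.

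Covered bases followed the staining of cytogenetic bands, a coarse marker of gene density and replication time. The darkest bands (gpos100), which are gene-poor and replicate late, held 8.06% of covered bases against 16.02% in placements with each island kept on its chromosome (0.50 times, 95% range 15.14 to 16.98%). The next darkest (gpos75) held 0.73 times the placed share. Pale bands (gneg) held 1.09 times, and lightly stained bands 1.26 times (gpos25) and 1.21 times (gpos50). Bands of variable heterochromatin (gvar) held 1.92 times and centromere bands (acen) 2.63 times the placed share outside the excluded stretches. Of the 4 gvar bands tested against genome-wide placement, 19p12 and 21p11.2 were more covered. Band 19q12 at 10.4% was not called and 3q11.2 at 1.77% was less covered. All 7 classes passed (adjusted permutation p = 0.0020, the smallest possible). Among single bands, set against genome-wide placement, 40 of 81 gpos100 bands were less covered than placed and 1 was more covered, 14q31.3 at 21.8%. The 40 include bands of X, a chromosome low as a whole. Of these, Xq21.1 and Xq27.3 were not called against placements kept on X (adjusted permutation p = 0.67 and 0.077). Where placement was also allowed inside the island-free centromeric stretches, the shares of gvar and acen bands were 0.62 and 0.60 times those placed.

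Chromosome X carried few islands outside the tip of its short arm. Of its 39 tested bands, 28 were less covered than genome-wide placement, and 5 held no island. Against placements kept on X, 4 bands were lower (Xp21.3, Xp21.1, Xq21.31 and Xq25), and of the 5 bands without an island Xp21.3 passed. In Xp22.33, the band with the pseudoautosomal region shared with Y, 41 islands covered 20.7% of the bases (adjusted permutation p = 0.037), all of them ending by position 2935000. The rest of X was covered over 1.51%, below the placement range of 7.25 to 9.32%. At or beside its centromere, Xq11.1 at 9.10% and Xq11.2 at 10.7% were near the genome-wide placement level. Xq11.2 passed against placements kept on X (6.11 times, adjusted permutation p = 0.019). No island lay in the 10.8 Mb from 23447001 to 34267000 across Xp21, the region of the dystrophin gene, nor in the 9.68 Mb from 87082001 to 96765000 on Xq21. Band Xq26.2, the cytogenetic location of PHF6, held 3 islands over 2.56% of its bases and did not pass (adjusted permutation p = 0.10). Its neighbour Xq26.3, at 0.55%, was below genome-wide placement (adjusted permutation p = 0.018) but not below placement on X (0.29 times, adjusted permutation p = 0.18).

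Long island-free stretches also occurred on autosomes. Outside the centromeric stretches, 7 autosomal stretches reached 3 Mb, while the longest autosomal stretch of a placement had a median of 2.17 Mb and never exceeded 3.68 Mb. The longest, of 4.10 Mb, ran from 47741001 to 51837000 of chromosome 2 across 2p21 and 2p16.3. Others lay at 60420001 to 63634000 of chromosome 17 (3.21 Mb around 17q23.3) and 114132001 to 117270000 of chromosome 7 (3.14 Mb around 7q31.2, the band of MET and CFTR). In 7q31.2 islands covered 0.11% of the bases (adjusted permutation p = 0.018). Band 9p21.3, which holds the CDKN2A tumour suppressor gene often deleted in T cell leukaemia, was covered over 2.82% (adjusted permutation p = 0.028) and had no island from 21082001 to 23881000. Since no copy number or input value was used here, DNA missing from the cells at these stretches cannot be told apart from a lack of PHF6.

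The title of the series names satellite DNA, the repeat that builds centromeres, so distance from the centromeric gaps delimited here was compared with placement. Within 5 Mb of a gap lay 1006 islands, 8.73% of the list against 7.51% placed with each island kept on its chromosome (95% range 7.10 to 7.95%, 1.16 times, adjusted permutation p = 0.0023). The excess was strongest in the nearest Mb, with 331 islands or 1.86 times the placed share, and covered bases there were 2.99 times the placed share. From 1 to 2 Mb there were 204 islands against 175 placed (1.17 times, unadjusted permutation p = 0.024), and over 1 to 5 Mb the share was 5.86% against 5.97% placed (permutation p = 0.59). The gaps were delimited from the list itself, so that 43 islands border a stretch left out by construction. Without them the ratio was 1.12 within 5 Mb and 1.63 within 1 Mb, both with permutation p = 0.0020. For the full list, the ratio within 5 Mb turned from 1.16 to 0.68 where placement was also allowed inside the gaps. Whether islands hold satellite sequence was not analysed here.

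Toward chromosome ends the excess was broader. Within 5 Mb of an end lay 1268 islands, 1.48 times the placed share of 7.41% of the list (95% range 7.02 to 7.87%, adjusted permutation p = 0.0023), and from 1 to 5 Mb the ratio was 1.50. In the last 0.1 Mb the 15 islands were 0.83 times the placed share (adjusted permutation p = 0.59), while covered bases there were 1.77 times (adjusted permutation p = 0.10). The end bands 4q35.2 at 38.7%, 12q24.33 at 35.8%, 20q13.33 at 21.8% and 5p15.33 at 19.4% were among those more covered than placed.

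**Figure D4:**
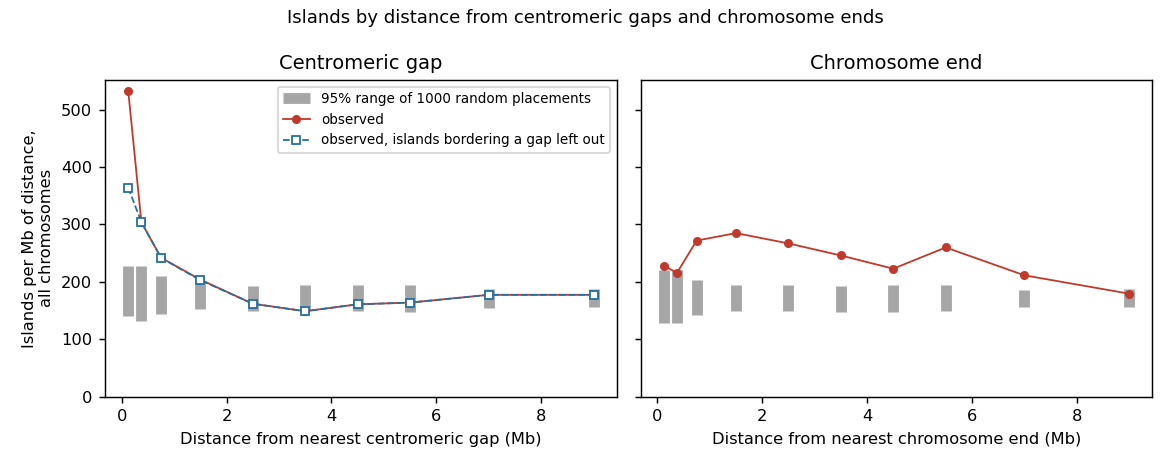
Islands per Mb of distance from the nearest centromeric gap (left) and the nearest chromosome end (right), summed over all chromosomes. Grey bars show the 95% range of 1000 random placements, and open squares the list without the 43 islands that border a stretch left out. In the nearest 0.25 Mb there were 133 islands beside gaps against a placement median of 45, and beside chromosome ends 57 against 43.

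Islands lay in clusters. Another island was within 10 kb for 2779 islands, 24.1% of the list against 5.49% placed (95% range 4.90 to 6.10%, 4.39 times), and within 50 kb for 52.1% against 35.0% (1.49 times, adjusted permutation p = 0.0023 for both). In the stricter list the ratio within 10 kb was 7.60. The shortest spacing of 4 kb was shared by 579 pairs, so a broad domain split in the calling could count as a cluster. Islands were not merged at 4 to 10 kb. When islands were reshuffled without overlap inside bins of 1 Mb, which keeps dense regions dense, the placed share was 8.33% and the ratio 2.89. When each island was moved at random by up to 500 kb and allowed to overlap others, overlapping islands counted as neighbours and the ratio turned to 0.91.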

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

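Settings added after seeing the data were placement over whole chromosome lengths, placement with each island kept on its chromosome, reshuffling in 1 Mb bins, a second set of placements, distance from centromere bands, the list without islands that border a gap and, for chromosomes and chromosome ends, covered bases. So was leaving out chromosome 19. Of 275 values compared with their main value, 237 kept their direction and side of the threshold, or stayed within 1.5 times for a count. The stricter list, built by length since no score was given, held 5847 islands with a median of 23 kb, and called 8 chromosomes higher and 5 lower. With autosomes only, 2 chromosomes were higher and 5 lower, and by covered bases 5 were lower. The placed level rises without X by construction. Placement over whole chromosome lengths also fills the stretches left out, and how much assembled sequence they hold was not checked. It reversed the ratios near centromeric gaps (0.68), in gvar bands (0.62), in acen bands (0.60) and for chromosome 22 (0.92). Moving islands within 1 Mb windows with overlaps allowed reversed clustering (0.91). With each island kept on its chromosome, which sets bands against their own chromosome, 19p13.2 (1.00) and 19q13.42 (0.94) stood just below their placed level and Xq28 above it (2.025). Merging within 1 kb, which joins nothing since no gap was under 4 kb, is not counted. Single bands and chromosomes lost their call in 25 comparisons and Xq28 gained one (lower, without islands that border a gap). Band 6p12.2, which held no island, lost its call in all 6 of its alternatives (adjusted permutation p = 0.057 to 0.35). No paired analysis was possible because each genotype had 1 library and the list holds no value per library. The tests planned on satellite sequence, repeats, gene features, gene lists and density by gene number were not run. With no reads or scores, neither depth nor the caller's threshold could be varied.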

Other observations

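Apart from the tests of the 8 zinc finger bands outside chromosome 19 and of Xq28 against genome-wide placement, the tests in this part were chosen only after the result was seen. Ends of autosomes differed from one another. Of 39 terminal autosomal bands tested, 7 were more covered than placed and 0 less, with a median of 12.7% and a range of 2.36 to 52.8%. Bands of chromosome 13, which is gene-poor, were called lower in 6 of 30 cases and higher in 0, and those of chromosome 2 lower in 8 of 60 and higher in 1. Over all tested bands 95 of 762 were lower and 40 higher, so the lower share on chromosome 2 was near that of the genome.

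Covered bases of chromosome 19 were unevenly spread, and several of its most covered bands are known for clusters of zinc finger genes. A gain of the whole chromosome or of an arm would raise every band. The lowest band stood at 7.57% (19q13.32) and the lowest on the short arm at 8.94% (19p13.3). Both lay inside their placement ranges, as did 5 of 15 bands in all. An even gain alone would therefore not account for the differences between bands. Whether a gain adds to them cannot be told, because the level each band would have without it is unknown. The 6 bands of chromosome 19 picked for such clusters (51.7% covered, against 13.2% in its 9 other tested bands) were chosen after they were seen to be high, so this value decides nothing. In 8 such bands elsewhere, picked from general knowledge before their values were seen, islands covered 14.9% against 8.18% placed (6.75 to 10.1%), with 4p16.3, 7q36.1 and 16p11.2 called and 16p13.3 at 6.04%. The value outside chromosome 19 is consistent with islands following zinc finger clusters, as a hypothesis, but 4p16.3, 8q24.3, 16p13.3 and 1q44 are also end bands, local gains and repeats shared by gene copies remain open, and no gene was assigned.

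The excess beside centromeric gaps may come from satellite-like repeats that are collapsed at gap edges, where reads of many copies pile up, or from PHF6 on pericentromeric chromatin. Collapsed repeats predict no excess farther out, and the share of islands from 1 to 5 Mb was 0.98 times that placed, which both explanations allow. Islands were 1.17 times those placed from 1 to 2 Mb and 0.95, 0.88 and 0.94 times in the next 3 bins of 1 Mb. Covered bases from 1 to 5 Mb, in the list without islands that border a gap, were 1.12 times the placed share (unadjusted permutation p = 0.022) but 1.04 times without chromosome 19 (permutation p = 0.38). Band 19p12 also lies beside a gap, so islands that follow zinc finger clusters could add to the excess there. Without chromosome 19 the share of islands within 1 Mb was still 1.84 times that placed (permutation p = 0.0020). Zinc finger bands beside other gaps were not tested. These explanations cannot be told apart without reads, repeat sequence or an input library.

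The few islands on X might reflect fewer copies of X than of autosomes, with less coverage to call islands from. This predicts an ordinary level in the pseudoautosomal end, which has a second copy on Y. Band Xp22.33 was covered over 20.7% against 1.51% for the rest of X. That was 2.59 times its genome-wide placement median and above the range of 3.88 to 14.9%. Fewer copies of X alone do not predict a level above the range. An excess at chromosome ends would raise Xq28 as well, and Xq28 was covered over 3.97%, below its genome-wide placement range of 4.82 to 12.9%, but 2.025 times the median where islands were kept on X (range 0.87 to 3.57%, adjusted permutation p = 0.10), against 10.9 times for Xp22.33. The genome-wide range was too strict a bar for an end of a chromosome that is low throughout, so an end excess is not excluded, and copy number, mapping and a true lack of PHF6 on X stay open too. No copy number or input value was used here, and a biological explanation was not tested.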
